A study of Mus musculus with 6 samples.

How the data were processed

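Whole skin biopsies of mouse wound scars were measured on Affymetrix exon arrays, which carry probes along each exon and report a level per transcript cluster. There were 6 samples, 1 from a mouse with high and 1 from a mouse with low follicle regeneration at each of days 4, 6 and 9 after wound closure. The design text describes the low group as having no regenerated follicles, while the sample labels call it low. Per the labels' protocols, biopsies were kept in RNAlater, RNA was extracted with a kit for fibrous tissue, and total RNA was amplified in 1 round with random primers.

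The deposited values were on a log2 scale, a unit read from their range on every array, since no label states it. Per the submitters' processing notes, Affymetrix Expression Console and PLIER (an algorithm that combines the probes of a set into a level) were used, with no version, role or order given. The genome build, the background correction and any filter are not given in the sources used here. Array medians over all 53145 rows differed by at most 0.055 log2 units, below the limit of 0.1 set beforehand, so no further normalization was applied.

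Rows were named through the platform annotation. Of the rows, 25466 had 1 gene symbol, 2299 had several and 25380 had none in the table used. Of those with 1 symbol, 24868 were matched by gene identifier to a table for the mouse assembly GRCm38.p6, and 0 symbols needed an update. Rows with several symbols named no gene, so genes that share probes with a near-identical copy are missing from the gene lists. The row of highest mean was kept for each of the 3090 genes with more than 1 row, which gave 20255 genes. The lowest 25% of genes by mean level were left out (mean below 5.60 log2 units), leaving 15191.

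High and low regeneration were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with day as a factor with 3 levels. The block rests on the design text, which states that the samples of a pair shared a date. As a check, same-day samples deviated together from their group means across genes, with correlations of 0.5, 0.112 and 0.56 at days 4, 6 and 9. The day 6 pair was no more alike than some samples of different days (0.141 for high day 4 with low day 6, 0.112 for high day 6 with low day 9), and the other different-day values were from -0.491 to -0.242. Change over time was the slope per day with the group as a covariate. That fit held no term for the pair, since day and pair coincide, so samples that shared a date counted as independent. Day after closure cannot be told apart from the date, and the slope p-values may be too small. The difference in slope between the groups was their interaction. These fits left 2, 3 and 2 residual degrees of freedom. The labels do not say whether any samples share an animal, and p-values measure the spread between these samples. The number of arrays limits the precision of every value.

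Fixed before the data were examined were 35 gene lists, the tests, the alternatives and the rule for named genes. The 33 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. They were tested again with a correlation estimated per list and with fry. With an estimated correlation camera uses the residual degrees of freedom, so with 2 or 3 of these it has little power to call a list. The lists of red blood cell genes and sex-linked genes had 3 and 4 measured members and were not tested. Named genes were up to 12 per direction that passed the test with 1 sign in all 3 pairs, largest change first. Free places went to the genes of lowest unadjusted p with 1 sign in all pairs and a log2 change of at least 1, given as values that did not pass. Up to 4 members of lowest p of each list that passed were added, with Ptgds, Ptgdr2, Tlr3, Fgf9, Il6, Shh and Wnt7a in any case. For the slope the sign was that of day 9 minus day 4 in both groups.

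The tests were run on simulated data for the 15191 genes, 20 data sets per setting with 200 changed genes each. With variances drawn from the fitted prior distribution, limma recovered 16% of genes that differed by 0.5 log2 units between high and low, 86.2% at 1, 95.2% at 1.5 and 97.1% at 2, and 4.51% of its calls were false. With each gene's residual variance in place of the prior, 3.16% were false, and with each gene's moderated variance 8.21%. With the fitted prior there were 154 calls per data set, where the real comparison gave 8. The adjustment is stricter when fewer genes change, so these recovered shares may be too high for the real data. The first simulation had used the moderated variances in a single data set and made more false calls than the nominal rate, after which all 3 variance models were run and are given here. For the slope, 10.3% of genes were recovered at 0.1 log2 units per day and 79.3% at 0.2, with 5.21% of calls false for the fitted prior, 4.38% for the residual and 6.61% for the moderated variances. For the difference in slope, 0% were recovered at up to 0.4 log2 units per day with the fitted prior or the residual variances. With the moderated variances, 90.9% were recovered at 0.4 and 10.2% of calls were false. In 50 simulated data sets with no effect, camera with the preset correlation called 0.1% of lists when members were independent and 47.5% when members shared a correlation of 0.8. With the estimated correlation it called 0% in both cases, and fry called 0.3% and 0.2%.

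Alternatives were quantile normalization, no filter or a stricter filter on dim genes, the mean of all rows of a gene, a variance trend with robust estimation, fits without the day term or with day as a number, day 9 against day 4, no group term, and leaving out each pair or sample. The planned pseudocount did not apply, since the values were already logarithmic. Leaving out each sample in the test of the difference in slope, for genes and lists, was added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to name rows and draw figures.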

Results

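Large skin wounds in mice can form new hair follicles within the scar, a process called wound-induced hair neogenesis, and animals differ in how many follicles they form. Transcript levels were measured in 6 scar biopsies, 3 from mice with high and 3 from mice with low regeneration, with 1 of each at days 4, 6 and 9 after wound closure. Array medians lay between 6.04 and 6.10 log2 units. Samples of a day pair correlated at 0.984, 0.988 and 0.987 at days 4, 6 and 9, across rows with 1 gene symbol. Samples of different days correlated at 0.968 to 0.990, so the pairs did not stand out. Rows are not independent replicates. The first principal component held 50.3% of the variance and ran from the high-regeneration sample of day 4, at -34.5, to the low-regeneration sample of day 9, at 24.1.

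The first comparison asked which transcripts differed between scars with high and low regeneration at matched days. Fos, Fosb, Nr4a1 and Nr4a3, immediate early genes that cells switch on within minutes of a stimulus, were higher in the high-regeneration scars at all 3 days. Among the genes that passed, Ptgs2, the inducible enzyme of prostaglandin synthesis, differed most, by 1.90 ± 0.21 log2 units (SD of 3 pairs, 3.72-fold, adjusted p = 0.0381). Shh, the hedgehog ligand made by hair germs, was higher by 1.28 ± 0.15 (adjusted p = 0.0476), with differences of 1.28, 1.13 and 1.42 at days 4, 6 and 9. Cxcl1, a chemokine that draws neutrophils, was higher by 1.08 ± 0.09. Markers of the hair shaft and inner root sheath were higher at days 4 and 9, and interferon-induced genes were lower, on list tests with a preset correlation, although no single gene of those groups passed with all 3 pairs. With an estimated correlation those list calls were lost (adjusted p = 0.543, 0.518 and 0.431), though camera then has only 2 residual degrees of freedom.

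In all, 8 of 15191 genes passed, and each was higher in the high-regeneration scars in 3 of 3 pairs. The others were Nr4a1 (1.55 ± 0.09), Fosb (1.52 ± 0.16), Fos (1.14 ± 0.05), Nr4a3 (1.14 ± 0.06) and Ifrd1 (0.99 ± 0.05), all SD of 3 pairs. Nr4a1 and Nr4a3 encode nuclear receptors induced as immediate early genes, and Fos and Fosb encode parts of the transcription factor AP-1. At an unadjusted p under 0.05 there were 1529 genes, 743 higher and 786 lower, where 760 would be expected by chance. Other groupings of the 6 samples gave 403 to 640 where they parted all 3 pairs. Groupings that parted 1 pair gave up to 1518, but with day as a block they compare high with low within that pair. They hold part of the real difference, so they cannot serve as a reference for the excess over 760. The groupings that part all 3 pairs are too few for a share under 0.05. Without the day 4 pair, without the day 9 pair, after quantile normalization and without the filter on dim genes, 0 genes passed, and without the day 6 pair 35 did. Those 35 held 5 of the 8 genes but not Fos, Nr4a3 or Ifrd1, and they included the inner root sheath keratin genes Krt25 and Krt73 and the interferon-induced genes Ifit1, Rsad2 and Usp18. Without the day term 6 passed, among them Nr4a1, Fosb, Fos, Cxcl1 and Ifrd1 but not Ptgs2, Shh or Nr4a3.

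**Figure D1:**
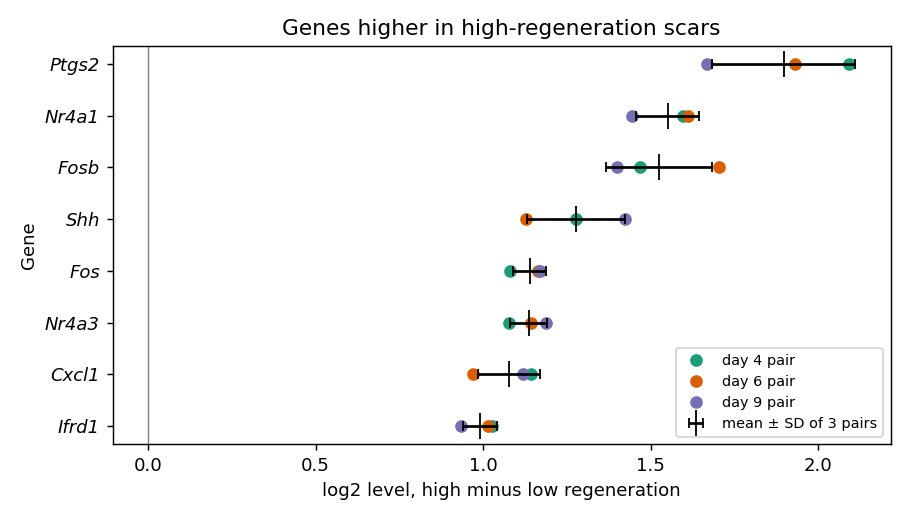
Log2 difference between high and low regeneration (horizontal axis) for the 8 genes that passed the test (vertical axis), with a point for each day pair and a bar for the mean ± SD of the 3 pairs. Each point lies above 0, from 0.93 for Ifrd1 at day 9 to 2.09 for Ptgs2 at day 4.

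Of the list of immediate early and heat shock genes, 14 of 15 measured members were higher in all 3 pairs. The genes Fos, Fosb and Nr4a1 passed over all genes tested, and 13 passed when adjusted over the list alone. The list median was 0.72 (adjusted p = 4.17e-20 with the preset correlation, adjusted p = 0.431 with an estimated correlation). Zfp36, which encodes a protein that destabilises cytokine messages, differed by 0.91 ± 0.12 (SD of 3 pairs, adjusted p = 0.106), and Atf3, a stress-induced transcription factor, by 1.39 ± 0.34 (adjusted p = 0.135). The member with the opposite sign was Hspa1a, a heat shock chaperone, at -0.15.

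Inflammatory cytokines and chemokines were higher with a list median of 0.22 (adjusted p = 4.38e-06 with the preset correlation, adjusted p = 0.431 with an estimated correlation). Of 17 members, 1 passed over all genes, and 7 higher and 2 lower passed when adjusted over the list alone. Without the day 9 pair the median was 0.34. Beside Cxcl1, the values of Osm (0.55), Ccl3 (0.84) and Socs3 (0.59) did not pass over all genes. Whether handling of the tissue raised the genes of this list was not tested. Il6 lay below the filter on dim genes. Its log2 levels were 6.21, 5.79 and 6.68 in the high-regeneration samples of days 4, 6 and 9, against 4.14, 4.61 and 4.70 in the low (adjusted p = 0.207 without the filter).

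Hair-forming genes were higher in the high-regeneration scars on the list tests. The inner root sheath list had a median of 1.41 over 13 members (adjusted p = 1.07e-06, and adjusted p = 0.518 with an estimated correlation). The hair shaft list had a median of 0.88 over 17 members (adjusted p = 9.56e-06, and adjusted p = 0.543 with an estimated correlation). Neither difference was even across days. The inner root sheath medians were 2.19, -0.039 and 2.12 at days 4, 6 and 9, and the hair shaft medians were 2.28, -0.64 and 1.03. Krt73, a keratin of the inner root sheath, differed by 2.22 ± 1.14 and Krt25 by 1.72 ± 1.13. Krt35, a hair shaft keratin, differed by 1.62 ± 1.24 and Dsg4, a desmosomal cadherin of the hair, by 1.77 ± 1.19 (all SD of 3 pairs). None of these 4 genes passed over all genes. Without the day 4 pair the hair shaft median was 0.33, and without the day 6 pair it was 1.79. In the same day 4 pair, skeletal muscle genes had a median of 0.93, melanocyte genes 0.60 and adipocyte genes 0.53. Wound-edge keratinocyte genes had pair medians of 0.75, -0.64 and -0.14 at days 4, 6 and 9 (adjusted p = 0.156). At day 9 the inner root sheath genes stood at 0.11 relative to their means in the high-regeneration sample and at -1.88 in the low, which was also the only sample with a high Xist level and held Krtap7-1, Krtap9-3, Prr9 and AI506816 at least 2 log2 units below all others. Y-linked genes were low in that sample too, so the day 9 difference cannot be told apart from sex. In the high-regeneration sample of day 4, 35 genes stood at least 2 log2 units above every other sample, mostly keratins and keratin-associated proteins. That sample also stood apart at the histocompatibility genes H2-Ea and H2-Ob. The day 4 difference thus cannot be told apart from one in genetic background.

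Lists of the early follicle and its signals had smaller medians. The hair placode and matrix list had a median of 0.29 over 18 members, of which 11 were higher in all 3 pairs (adjusted p = 4.03e-07, and adjusted p = 0.431 with an estimated correlation). Msx2, a transcription factor of the hair matrix, differed by 0.78 ± 0.29 and did not pass. The hedgehog list had a median of 0.11 (adjusted p = 0.00125), with Gli1, a target of hedgehog signalling, at 0.39 ± 0.15. The dermal papilla list had a median of 0.21 (adjusted p = 0.00187) and the list of Wnt feedback and target genes 0.11 (adjusted p = 0.00376). Both held Wif1, a secreted Wnt inhibitor, at 1.08 ± 0.55. The BMP list had a median of 0.072 (adjusted p = 0.0135), with Id1, a direct target of BMP signalling, at 0.52. The hair follicle stem cell list had a median of 0.064 (adjusted p = 0.0405). With an estimated correlation, adjusted p was 0.431 for the hedgehog, dermal papilla, Wnt and BMP lists and 0.529 for the stem cell list. Without the day 6 pair the hedgehog median was 0.071 and the Wnt median 0.070. The stem cell list did not pass without the day term, without the day 4 pair (median 0.072) or without the day 9 pair (median 0.016), and was at 0.19 without the day 6 pair. The BMP list did not pass without the day 4 pair (median 0.034) or the day 9 pair (0.082), and was at 0.19 without the day 6 pair.

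The list of reported regulators of hair neogenesis had a median of 0.17 over 15 members (adjusted p = 0.000419, and adjusted p = 0.431 with an estimated correlation). The list was not divided into genes that promote and genes that inhibit neogenesis, so the sign of its median cannot be read as either. Without the day 6 pair the median was 0.063. Its members Shh, Msx2, Edar and Msx1 (0.076) are also on the placode list. Il1b, an inflammatory cytokine, differed by 0.95 ± 0.39 and did not pass. Fgf9, a growth factor, differed by 0.17 ± 0.09 (adjusted p = 0.496), Tlr3, the receptor for double-stranded RNA, by -0.28 ± 0.24 (adjusted p = 0.494) and Wnt7a by 0.026 ± 0.12 (adjusted p = 0.931). The prostaglandin list did not pass (median 0.037, adjusted p = 0.134). Ptgs2 was the only member of 18 that passed over all genes. Ptgds, a synthase of prostaglandin D2, differed by 0.27 ± 0.23 (adjusted p = 0.494) and its receptor gene Ptgdr2 by 0.051 ± 0.19 (adjusted p = 0.882).

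Interferon and double-stranded RNA response genes were lower in the high-regeneration scars, with all 21 measured members negative and a list median of -0.68 (adjusted p = 3.56e-16, and adjusted p = 0.431 with an estimated correlation). Over all genes 0 members passed, and 15 passed when adjusted over the list alone. The list medians were -0.81, -0.29 and -1.08 at days 4, 6 and 9. Stat2, a mediator of interferon signalling, differed by -1.02 ± 0.34, Isg15 by -1.01 ± 0.33, Zbp1 by -0.88 ± 0.26 and Irf7 by -0.63 ± 0.16, without passing over all genes. T cell genes were lower with a list median of -0.36 (adjusted p = 4.7e-06, and adjusted p = 0.431 with an estimated correlation), with Gzmb at -1.13 ± 0.74, Cd3g at -0.82 ± 0.53 and Il2rb at -0.65 ± 0.17. The low-regeneration sample of day 9, which had the highest interferon level, was also the only sample with a high Xist level (12.77, against 5.75 to 7.30 in the others). Its Y-linked genes were low as well, the pattern of a female. Group and sex thus cannot be told apart in the day 9 pair. Without the day 9 pair the interferon median was -0.62 and the T cell median -0.25.

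Markers of other cell types moved with the group as well. Skeletal muscle genes had a median of 0.42 (adjusted p = 1.53e-05, and adjusted p = 0.543 with an estimated correlation), with pair medians of 0.93, 0.14 and -0.0067 at days 4, 6 and 9, and without the day 4 pair the median was 0.10. Melanocyte genes had a median of 0.23 (adjusted p = 0.000207, and 0.431 as adjusted p with an estimated correlation), with Mlana at 0.48 and Dct at 0.52, and a median of 0.097 without the day 4 pair. Mast cell genes had a median of 0.21 (adjusted p = 0.00557, estimated-correlation adjusted p = 0.518), Schwann cell genes 0.081 (adjusted p = 0.0495, estimated-correlation adjusted p = 0.431) and mitosis and DNA replication genes 0.15 (adjusted p = 1.53e-05, estimated-correlation adjusted p = 0.518). Without the day 4 pair the mitosis median was 0.064. The mast cell list did not pass without the day 6 pair (median 0.11) or without the day term, nor did the Schwann cell list without the day 6 pair (0.15), the day 9 pair (0.050) or the day term. Sebocyte (adjusted p = 0.555), basal keratinocyte (adjusted p = 0.508), macrophage (adjusted p = 0.496) and scar matrix genes (adjusted p = 0.936) did not pass. Of the 33 lists, 18 passed with the preset correlation, 16 higher and 2 lower, and 0 passed with an estimated correlation or with fry, whose lowest adjusted p was 0.0596. At an unadjusted p under 0.05, 2 lists passed with an estimated correlation and 9 with fry. Lists with an estimated correlation below the preset 0.01 lost their calls too. The dermal papilla list (-0.0027) went from an unadjusted p of 0.000736 to 0.0675 in camera. The loss thus does not rest on correlation alone. With an estimated correlation camera uses the residual degrees of freedom, 2 in this fit, which leaves little power. The immediate early and heat shock list went from an unadjusted p of 1.26e-21 to 0.0231 in camera. A lost call therefore does not show that a list did not differ. How often a true list difference would be found was not simulated. In simulated data with no effect and a correlation of 0.8 among members, the preset correlation called 47.5% of lists. The estimated correlation was 0.91 for the hair shaft list, but 0.107 for immediate early and heat shock genes and -0.017 for the Wnt list. That share therefore does not apply to every list that passed.

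**Figure D2:**
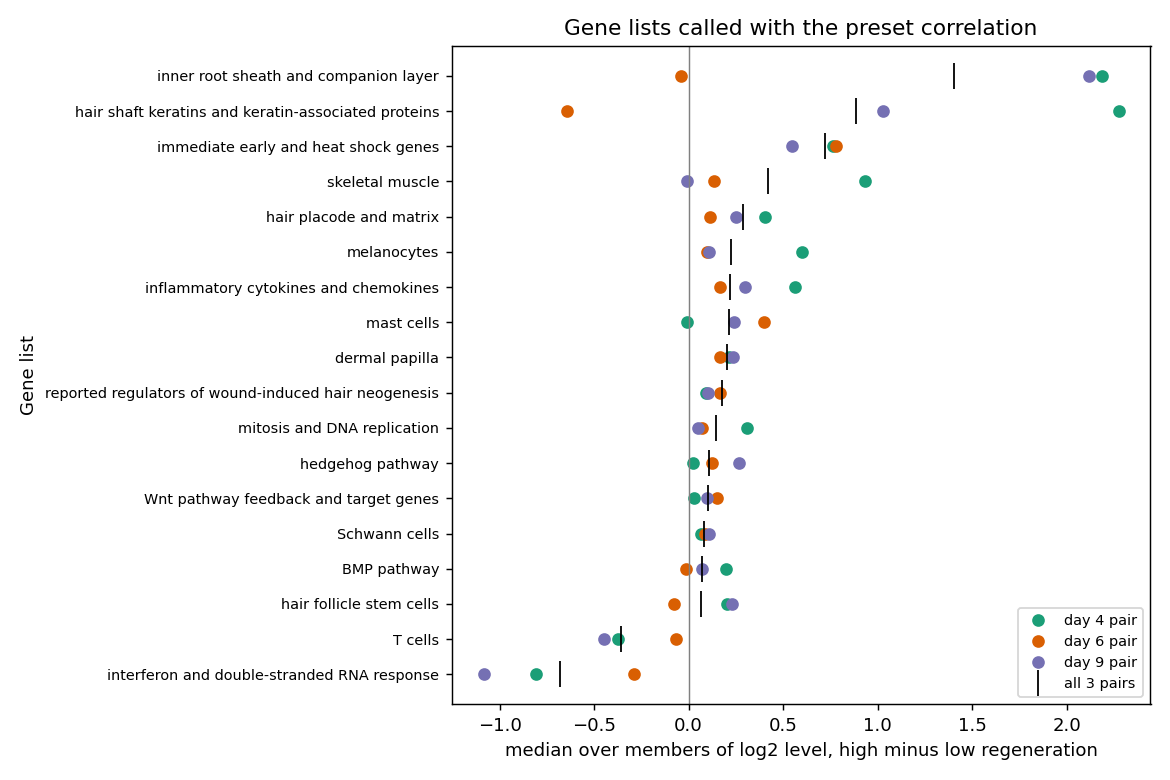
Median log2 difference between high and low regeneration over the members of each gene list (horizontal axis) for the 18 lists that passed with the preset correlation (vertical axis), with a point for each day pair and a tick for all 3 pairs. Inner root sheath genes lie at 2.19 and 2.12 at days 4 and 9 and at -0.039 at day 6, while the immediate early list lies between 0.55 and 0.78.

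The next comparison asked which transcripts changed from day 4 to day 9 after wound closure, with the regeneration group as a covariate. Samples that shared a date counted as independent in this fit, and day cannot be told apart from date. Sebaceous and hair shaft genes went down over these days in both groups, and interferon response, endothelial and scar matrix genes went up, on the list tests with a preset correlation. With an estimated correlation none of these list calls held (lowest adjusted p = 0.529), though camera then has only 3 residual degrees of freedom. No single gene passed, with a lowest adjusted p of 0.0714 in limma and 2457 genes at an unadjusted p under 0.05, of which 1054 were higher and 1403 lower.

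The sebocyte list had a median slope of -0.27 log2 units per day (adjusted p = 1.22e-13, and adjusted p = 0.529 with an estimated correlation). All 12 members were lower at day 9 than at day 4 in both groups, and all 12 passed when adjusted over the list alone. Fa2h, a fatty acid hydroxylase, had a slope of -0.45 ± 0.04 (SE), with day 9 minus day 4 of -2.36 in the high and -2.20 in the low group. Scd3, a fatty acid desaturase of sebaceous glands, had -0.39 ± 0.05 and Far2, a fatty acyl reductase, -0.23 ± 0.03. Ces1d had -0.32 ± 0.02 (SE, adjusted p = 0.0714) and Aadacl3 -0.59 ± 0.06 (SE, adjusted p = 0.1). Hair shaft genes had a median slope of -0.50 (adjusted p = 8.95e-10, and adjusted p = 0.529 with an estimated correlation) and inner root sheath genes -0.38 (adjusted p = 1.98e-06, and adjusted p = 0.529 with an estimated correlation). Krtap7-1, a keratin-associated protein, had a slope of -1.19 and Krt72 -0.58. Without the high-regeneration sample of day 4 the hair shaft median was -0.30 and the inner root sheath median -0.25. A changing share of unwounded haired skin in the biopsies was not tested as a source of these slopes.

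Melanocyte (-0.11, adjusted p = 0.000461), adipocyte (-0.10, adjusted p = 2.31e-05), skeletal muscle (-0.12, adjusted p = 3.01e-05), hair placode (-0.061, adjusted p = 0.000839) and retinoid lists (-0.033, adjusted p = 0.0436) also had negative median slopes per day. Dct, an enzyme of melanin synthesis, had a slope of -0.42, and Car3, a carbonic anhydrase abundant in fat, -0.44. Without the high-regeneration sample of day 4 the median was -0.043 for skeletal muscle and -0.063 for adipocytes, and the placode list did not pass (-0.029). Without the low-regeneration sample of day 9 the skeletal muscle median was -0.19. The retinoid list did not pass when any of 4 samples was left out, with medians of -0.045 and -0.035 without the low-regeneration samples of days 4 and 6, and -0.034 and -0.043 without the high- and low-regeneration samples of day 9. Interferon response genes had a median slope of 0.12 (adjusted p = 6.42e-10), with all 21 members positive and Isg15 at 0.18. Relative to gene means, their level at days 4, 6 and 9 was 0.11, 0.11 and 0.87 in the low group. In the high group it was -0.74, -0.18 and -0.22. The rise in the low group thus came with its day 9 sample, which had the sex-linked pattern of a female. Endothelial genes had 0.030 (adjusted p = 0.000405), with Emcn at 0.090, and scar matrix genes 0.034 (adjusted p = 0.00161), with Loxl2, a collagen cross-linking enzyme, at 0.083 and Fap at 0.11. Without the low-regeneration sample of day 4 the endothelial median was 0.017. The scar matrix median was 0.018 without the high-regeneration sample of day 4, and 0.022 without that of day 9, where the list did not pass. With an estimated correlation adjusted p was 0.529 for each of these lists, and 0 of the 11 lists passed with it or with fry (lowest adjusted p = 0.0824), where 0 and 4 lists were under an unadjusted p of 0.05. The gene of lowest unadjusted p, Sec61b, had a slope of 0.21 ± 0.01 (SE, adjusted p = 0.0714). Xist had a slope of 0.72, which came from the low-regeneration sample of day 9 (day 9 minus day 4 of 0.0058 in the high and 6.99 in the low group). Without the high-regeneration sample of day 6, 130 genes passed, 16 higher and 114 lower, and without the group term 7 did.

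**Figure D3:**
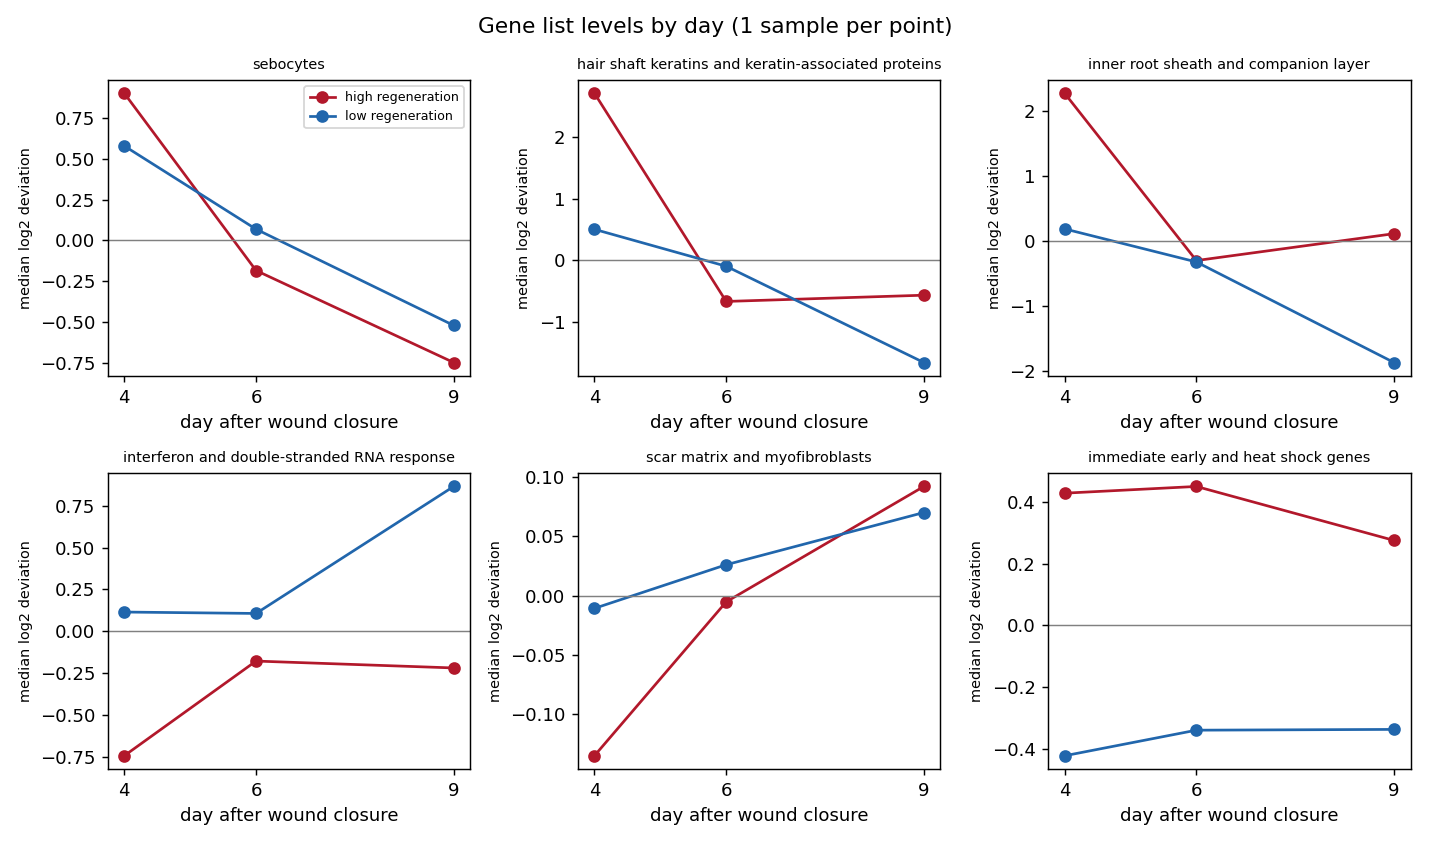
Median deviation of list members from their mean over the 6 samples, in log2 units (vertical axis), against day after wound closure (horizontal axis), with 1 sample per point, red for high and blue for low regeneration. Sebocyte genes run from 0.90 to -0.74 in the high group and from 0.58 to -0.52 in the low group, and immediate early genes stay above 0.27 in the high group and below -0.33 in the low group.

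The last comparison asked whether the change over days differed between the groups. In limma 0 genes passed (lowest adjusted p = 0.988), and 602 were under an unadjusted p of 0.05 where 760 would be expected by chance. The simulated data showed that this test recovered 0% of genes whose slopes differed by up to 0.4 log2 units per day for 2 of the 3 variance models, so the count does not show that the slopes were alike.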

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

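The tests of the 3 patterns below were chosen only after the result was seen, as was leaving out samples in the test of the difference in slope, while that test with all samples and the counts of sample splits were planned. The slope per day differed between high and low regeneration for 10 of 33 gene lists in the interaction fit with the preset correlation, and for 0 with an estimated correlation (lowest adjusted p = 0.883) or with fry (0.888), where 0 and 1 lists were under an unadjusted p of 0.05. The median slope in the high minus that in the low group, in log2 units per day, was -0.18 for skeletal muscle, -0.13 for wound-edge keratinocytes, -0.11 for adipocytes, -0.068 for melanocytes, -0.052 for mitosis and DNA replication, -0.046 for interferon response and -0.027 for T cell genes. It was 0.091 for Langerhans and dendritic cells, 0.059 for dermal fibroblasts and 0.032 for scar matrix genes. There was 1 sample per group and day, and these medians, other than that of scar matrix genes (0.029 to 0.036), moved by over 1.5 times when some single samples were left out. Without the high-regeneration sample of day 4, the difference was 0.0047 for skeletal muscle, 0.00076 for adipocytes, -0.014 for melanocytes, -0.025 for mitosis, -0.0039 for Langerhans and dendritic cells and -0.0064 for dermal fibroblasts, none of which passed, and wound-edge keratinocytes turned to 0.057. T cell and interferon genes were then at -0.12 and -0.17. Without the low-regeneration sample of day 9, 0 lists passed with the preset correlation, and without that of day 4, 4 did. Without the high-regeneration sample of day 9, 19 passed, T cell (0.088) and interferon genes (0.15) turned positive, and the T cell and scar matrix lists did not pass. Without the high-regeneration sample of day 6 the interferon list did not pass (-0.028).

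The 6 samples allow 10 splits, too few for a share under 0.05. The real split gave 8 genes and the highest other split 0, so 1 of 10 gave as many. For the gene lists with the preset correlation the real split gave 18 and the highest other 20, so 2 of 10 gave as many. Of the 10 splits, 4 part all 3 day pairs, the split with 20 lists among them, and the other 6 rest on a single pair each. With day as a block those 6 compare high with low within that pair and repeat the same fits. They hold part of the real difference, so counts out of 10 overstate the reference. Among the 4, the highest other split gave 0 genes and 20 lists.

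The first pattern is the higher level of immediate early genes in the high-regeneration scars at each day, a list call lost with an estimated correlation (adjusted p = 0.431). A larger share of cells that build the hair shaft and inner root sheath is argued against for the day 6 pair, where those genes had a median difference of -0.191 and the 13 immediate early genes a median of 0.787 with a lower quartile of 0.707. Stress or delay while the tissue was taken may also raise immediate early genes. The 7 chaperones measured had pair medians of 0.17, 0.0652 and 0.0388 at days 4, 6 and 9, with Dnajb1 at 0.38, 0.379 and 0.21 and Hsp90aa1 at 0.17, 0.224 and 0.0735, which does not decide, so handling cannot be told apart from a difference in the scars. For Ptgs2, Cxcl1, Ifrd1 and the cytokine genes, handling was not tested either, so the same limit holds for them. The difference in regeneration itself was not tested as the source.

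The second pattern is the higher level of hair shaft and inner root sheath genes at days 4 and 9. A larger share of unwounded haired skin, with its sebaceous glands, had no sign in the sebocyte genes of the day 9 pair. Their median was -0.0757 against 1.03 for the hair shaft. This does not exclude such a share, since a log2 difference also depends on the level already in the scar. The samples of that pair also differed in sex-linked genes. For the day 4 pair such a share cannot be told apart either. There the sebocyte median was 0.182 against 2.28 for the hair shaft, but skeletal muscle (0.93), melanocyte (0.60) and adipocyte genes (0.53) were higher too. Whether the pattern rests on the high-regeneration sample of day 4 stays open, since the inner root sheath median of 2.12 in the day 9 pair is part of how the pattern was found and comes with a low level in the low-regeneration sample (-1.88, against 0.11 in the high and 0.18 in the low-regeneration sample of day 4). The growth stage of follicles next to the scar and the new follicles themselves stay open and were not tested.

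The third pattern is a group of Skint genes, which encode epidermal immunoglobulin-like proteins, in the low-regeneration sample of day 6. Skint3 was at 4.01 there and at 9.02 or more in the other samples, and Skint4, Skint6 and Skint9 were also at least 2 log2 units below all others, with Skint11 lower there too (5.63, against 7.26 or more), and Skint7 was highest there (6.37). The 4 lie together on chromosome 4 in GRCm38.p6 (1e-04 of 10000 random draws, the smallest share these can give), but as members of a clustered family they would do so under any explanation, so this share decides nothing. A sequence variant or deletion in that animal and shared regulation of the family cannot be told apart. Loss of epidermal keratinocytes is argued against, since basal and differentiation genes had a median of 0.0106 there relative to the other samples, with a lower quartile of -0.0902.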

How the results depend on the processing

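The alternatives for the difference in slope without single samples, for genes and lists, were chosen after seeing the data. The 8 genes higher in high-regeneration scars were positive under each alternative that measured them, but 0 genes passed after quantile normalization (adjusted p of the 8 at most 0.0746) and 0 without the filter, where 20255 genes were tested. Without each pair in turn 0 to 35 genes passed, with 35 when the day 6 pair was left out (25 higher, 10 lower). The cause was not tested beyond the fewer samples in these fits. Without the replicate block 6 genes passed, Btg2 in addition and Ptgs2, Shh and Nr4a3 no longer, and the mast cell, Schwann cell and hair follicle stem cell lists did not pass. The block changed no other list call among those that passed. Those 3 lists also did not pass with day as a number, the Schwann and stem cell lists without the filter, and the Schwann cell list after quantile normalization. With an estimated correlation or fry, 0 lists passed for high against low and 0 for the slope, against 18 and 11. Over days, 0 genes passed with all samples, 7 without the group term, and 0 to 130 without single samples, with 130 when the high-regeneration sample of day 6 was left out. The difference in slope gave 0 genes with all samples and 0 to 83 without single samples, with 83 without the high-regeneration sample of day 9, where 1 residual degree of freedom remained. For the lists, differences in slope without the high-regeneration sample of day 4 and without that of day 9 were 0.057 and -0.37 for wound-edge keratinocytes, 0.00076 and -0.29 for adipocytes, 0.0047 and -0.52 for skeletal muscle, -0.0064 and 0.15 for dermal fibroblasts, -0.12 and 0.088 for T cells, -0.0039 and 0.26 for Langerhans and dendritic cells, and -0.17 and 0.15 for interferon response, 1 of each 2 with a reversed sign. Interferon response also reversed without the low-regeneration sample of day 9 (0.051). The signs of Ptgdr2 (-0.046 without the day 9 pair, 0.14 without the day 4 pair) and Wnt7a (-0.020 without the day 6 pair, 0.092 without the day 9 pair) reversed, both from values near 0, and the cause was not tested. Signal near background limits dim genes, such as Il6, which the filter left out.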

Other observations

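No test in this part was planned for these genes or levels beyond the tests over all genes. Some of the largest values between high and low were of genes outside the lists. Serpina3j, a serine protease inhibitor of the acute phase family, differed by -1.53 ± 0.66 log2 units between high and low (SD of 3 pairs, adjusted p = 0.23), with the same sign in 3 of 3 pairs. Tgtp1, an interferon-induced GTPase, was lower by at least 2-fold in all 3 pairs (-1.50 ± 0.59, adjusted p = 0.207), as was no other gene. In the other direction, Ugdh, an enzyme that makes the precursor of hyaluronan, was at 1.26 ± 0.24 (adjusted p = 0.107) and Tnfaip6, a hyaluronan-binding protein of inflamed tissue, at 1.33 ± 0.45 (adjusted p = 0.173). None of these values passed the test.

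Levels of sex-linked genes differed between samples. The low-regeneration sample of day 9 had an Xist level of 12.77 and levels of 4.36 for Eif2s3y, 4.98 for Kdm5d and 3.88 for Uty. In the other samples the lowest levels of those Y-linked genes were 7.10, 7.29 and 7.46. High Xist with low Y-linked genes is the pattern of a female, and the other samples held Y-linked signal. Differences in the day 9 pair, and changes to day 9 in the low group, thus cannot be told apart from sex. The low-regeneration sample of day 6 had Xist at 7.30 with Uty at 7.85. H2-Ea, a class II histocompatibility gene that is silent in some mouse strains, was at 6.59 in the high-regeneration sample of day 4 and at most 4.43 elsewhere, while H2-Ob was at 6.16 there and at least 7.68 elsewhere. The labels state neither sex nor strain. Whether that sample had another genetic background was not tested, so differences in the day 4 pair cannot be told apart from one in background.

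Among 18110 rows without a single gene symbol, 0 passed in the comparison of high and low in limma (lowest adjusted p = 0.548), and 1397 were under an unadjusted p of 0.05.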
